A study of Mus musculus with 74 samples.

How the data were processed

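The series holds 74 mouse 2-colour arrays in 11 groups. The groups named by their construct come from the DO11.10 T cell hybridoma, with untreated hybridoma cells as the second RNA on each array. These are 2 sets of empty retrovirus (MSCV_A, 12 arrays, and MSCV_B, 4 arrays), HDAC7-VP16 (10 arrays), MEF2D-VP16 (4 arrays), Nur77 (4 arrays), and a pair of groups treated with PMA and ionomycin for 2.5 h, one with the empty virus and one with the construct the labels call HDAC7 DP (8 arrays each). The other 4 groups hold 6 arrays each of thymocytes. One sets thymocytes of DO11.10 T cell receptor transgenic mice against those of mhc -/- mice, and the other 3 set thymocytes taken 3 h, 6 h and 12 h after injection of antigenic peptide against uninjected ones. The meaning of DP, the mouse strain and the sex of the animals are not given in the sources used here.

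Per the labels, total RNA was extracted with acid phenol and guanidinium, aminoallyl-dUTP was built into first-strand cDNA, and the cDNA was coupled to Cy3 or Cy5. The deposited values are log2 ratios of both channels of an array. The log base is assumed to be 2, because scanner, background correction, normalization, log base, direction of the ratio and filling of missing values are not given in the sources used here. Each array held 16463 probes and 0 missing values, so the planned filters on missing values moved nothing, and column medians lay between -0.021 and 0.023. One gene symbol was assigned to 14551 probes (13409 distinct symbols, with 1142 probes repeating a symbol), several to 6 and none to 1906, by the platform's own annotation. The Entrez ID of 14272 probes was found in the RefSeq gene table used here, and probe sequences were not aligned again. Spot intensities and backgrounds were not used here, so signal over background was not measured.

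Every group was labelled in both dye orientations in equal number, by the array titles. The label fields name Cy3 for both channels of every array, so the titles were used. The source name of HDAC7_VP16 replicate 1 names the empty virus while its title names HDAC7-VP16. It was kept in its group, and a fit without it was run. The direction of the ratios was read from the data: the median correlation over probes between arrays of opposite orientation was positive in 8 of the 11 groups (0.146 to 0.854) and negative in MSCV_A (-0.401), HDAC7_VP16 (-0.475) and MSCV_B (-0.241). The values were therefore taken as already turned to the test RNA over its partner. The sign of the whole series was likely right by Nr4a1 on the Nur77 arrays and by Egr1, Egr2, Nr4a1 and Il2 on the stimulated arrays. The direction of 2 MSCV_A arrays, replicates 3 and 9, remained unsettled. Same-dye correlations under -0.3 occurred in 10 of 171 Cy5 pairs and 9 of 171 Cy3 pairs of that slide set, always with one of these arrays. Counts with their sign turned are given with each comparison that uses them.

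Each array was centred on its median. For each of 11 comparisons limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0, in R 4.3.3) was fitted per probe to the groups compared, with a column for dye orientation. The empty-virus, MHC and peptide ratios were tested against 0. HDAC7-VP16 and stimulated empty-virus cells were set against MSCV_A, HDAC7 DP cells against stimulated empty-virus cells, and MEF2D-VP16 and Nur77 against MSCV_B. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, and rose, fell and changed are used of called genes alone. A moderated F test compared the 3 peptide times. The p-values measure the spread between arrays, which may be technical, since the labels do not say that arrays hold RNA of separate cultures or animals.

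Named genes follow a rule. The targeted genes come first. Then come the 8 highest and 8 lowest called probes with 1 symbol by log2 change, which for a ratio against 0 had to hold their direction on 80% of arrays. Last come up to 3 called members per gene list by size of change. A gene with several probes is given by the first in file order. For the difference between peptide times, 1 gene that the rule named is not reported here. The 19 gene lists were tested with camera at a preset correlation, and again with the correlation estimated from the data. Counts of called members are given over all probes and also adjusted over the list alone. Of 209 tests of a list in a comparison, 54 were called and 17 of these held with the estimated correlation. Where it ended the call of a list named below, its adjusted p is given. Not every called list is named. In 42 of the 209 the median, the mean and the direction of the test differed in sign, and 0 of these were called. Another 4 lists were written for the closing part: hypoxia-induced, Y-linked, cortical epithelium and medullary epithelium genes. In 16 relations, log2 changes of a pair of comparisons were correlated over probes. Genes are not independent replicates, so no p-value is given. For pairs sharing control arrays, 20 simulated unchanged groups and a split of the controls gave the part due to sharing, and for 2 of these pairs the overlap of calls was also counted with the controls split. The fits were tested on simulated data with 200 changed probes. At a log2 size of 2, between 92.4% and 100% were recovered, at 1 between 71.6% and 97%, and at 0.5 between 7.46% (MEF2D-VP16) and 74.6%. With 0 wrong signs, between 3 and 15 unchanged probes were called.

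The groups, comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. These alternatives were array weights, values left uncentred, arrays scaled to one spread, no dye term, probes of a gene averaged, all groups of a cell source in one fit, a log2 change of at least 1, slides of series 14 or 15 alone, slide number as a random block, ratios to untreated cells, all 16 empty-virus arrays as control, leaving out arrays of repeated slide numbers, and leaving out 1 array. Others were added after seeing the data: leaving out, turning the sign or exchanging the dye of the 2 unsettled arrays, averaging slides of one set, taking slide series as a block, and leaving out a pair of slides at 3 h or in the MHC comparison, or, for gene lists, at each peptide time. The labels number slides, not replicates, so no samples were paired.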

Results

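The arrays follow RNA changes made by HDAC7 and MEF2D fusion proteins and by Nur77 in a T cell hybridoma, by PMA and ionomycin in hybridoma cells, and by peptide in the thymus. HDAC7 is a class IIa histone deacetylase that is bound to DNA by MEF2 transcription factors and represses their targets, among them Nr4a1, the gene of the orphan receptor Nur77. Changes are log2 changes with standard error (SE), and a positive value is taken as more RNA with the named construct, stimulus or peptide.

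HDAC7 joined to VP16, a viral activation domain, raised a small set of T cell receptor-linked genes strongly. Cd28, the gene of a costimulatory receptor, rose 12.8-fold over the empty virus (log2 change 3.68, SE 0.21, adjusted p = 2.96e-10; 10 of 10 arrays above untreated cells). Nr4a1 rose 9.71-fold (3.28, SE 0.23, adjusted p = 1.16e-08; 10 of 10 arrays). The inhibitory receptor gene Pdcd1 rose 3.85-fold (1.95, SE 0.23, adjusted p = 1.67e-05; 10 arrays against 12). The receptors Cd6 (6.83-fold) and Cd5 (3.97-fold), the kinase-like regulator Trib1 (5.96-fold), the leukocyte adaptor Cytip (4.51-fold), the muscle enolase Eno3 (4.21-fold) and the activation-linked transcription factor Irf4 (4.09-fold) rose with them. So did Hdac5, the gene of another class IIa deacetylase (2.4-fold, adjusted p = 0.00144), the survival gene Bcl2 (0.86) and the thymocyte transcription factor gene Lef1 (0.94). The largest falls were in Ndrg1, a stress- and hypoxia-linked gene (7.83-fold lower; -2.97, SE 0.49, adjusted p = 0.000895), the selenium-binding protein gene Selenbp2 (-2.11), the mitophagy gene Bnip3 (-2.03), the cyclin gene Ccng2 (-1.99), the stress kinase-like gene Trib3 (-1.82) and the cytokine receptor gene Flt3 (-1.79). The zinc finger gene Egr1, which is induced early after stimulation, fell by 1.35. In all 447 probes were called, 234 higher and 213 lower, of which 55 changed at least 2-fold (32 higher). The count was 284 without a dye term, 238 with all 16 empty-virus arrays as control and 256 with slides of one set averaged. With all 16 as control 12 of 34 called named genes lost their call, among them Ndrg1 (-2.13), Selenbp2 (-1.14), Bnip3 (-1.35), Ccng2 (-1.22), Bcl2 (0.58) and Lef1 (0.74), and against untreated cells 8 of 34 did, Ccng2 (-1.16), Bcl2 (0.43) and Lef1 (0.60) among them. Hdac7 itself was 0.42 higher (SE 0.12, adjusted p = 0.0732) and Mef2d 0.18 higher, and neither was called. Hdac7 was called with slide series as a block (0.39, adjusted p = 0.0381), against untreated cells (0.55, adjusted p = 0.0302) and in series 15 alone (0.55, adjusted p = 0.0181), but not in series 14 alone (0.19).

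Among 24 T cell receptor signalling genes measured, 6 rose with HDAC7-VP16, 0 fell and 18 were not called (8 rose and 1 fell when adjusted over the list alone, camera adjusted p = 7.33e-05). Cd28, Cd6 and Cd5 led this list. Of 31 genes of mature single-positive thymocytes 6 rose, Cd5 and Bcl2 among them, and 4 fell, the homing integrin gene Itgb7 (-0.66) among them (10 and 4 over the list alone, camera adjusted p = 0.00607). In the list of T cell activation and cytokine genes 3 of 36 rose and 0 fell (camera adjusted p = 0.00607), Pdcd1 and Cd5 among them. Glucocorticoid-response genes went down: 4 of 12 fell and 0 rose (7 fell over the list alone, camera adjusted p = 0.000187), with the leucine zipper gene Tsc22d3 (-1.19), the phosphatase gene Dusp1 (-0.94) and the thioredoxin inhibitor gene Txnip (-0.61) lowest. The call of Dusp1 ended against untreated cells (-0.41) and with all 16 empty-virus arrays as control (-0.68), and against untreated cells Tsc22d3 stood at -0.77, Txnip at -0.99 and Itgb7 at -1.07. Immediate early genes were mixed, with 2 of 32 higher and 7 lower (camera adjusted p = 0.451). Their median (0.03) and mean (0.02) were positive while the test pointed down. The slides of series 14 alone called 7 probes (5 of them among the 447), with Irf4 (1.45) and Pdcd1 (1.83) no longer called, and those of series 15 called 703 (333 shared). Cd28 (3.84 and 3.58) and Nr4a1 (3.76 and 2.87) were called in both series. With the sign of both unsettled MSCV_A arrays turned, 401 probes were called and 299 were shared.

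PMA and ionomycin, which bypass the T cell receptor to activate protein kinase C and calcium signalling, induced the classical activation genes in empty-virus cells. Nr4a1 rose 31.7-fold (4.99, SE 0.26, adjusted p = 9.25e-11; 8 of 8 arrays), the chemokine gene Ccl1 30.6-fold (4.94, SE 0.57), the RANK ligand gene Tnfsf11 21-fold (4.39, SE 0.26) and Il2, the gene of the main T cell growth cytokine, 10.3-fold (3.37, SE 0.50, adjusted p = 8.8e-05). Nab2, a corepressor of EGR proteins, rose 16.4-fold, Egr2 14.6-fold, the apoptosis-linked Phlda1 13.6-fold and Irf4 10.8-fold. The death ligand genes Tnf (3.15) and Fasl (3.01), the repressor gene Bcl6 (2.95), Lef1 (2.24), the heat-stable antigen gene Cd24a (2.19), the stress sensor Gadd45b (2.11) and Cd28 (1.28) also rose. The falls were led by Ccng2 (6.01-fold; -2.59, SE 0.16), Trib3 (5.11-fold) and the sterol transporter gene Abcg1 (4.64-fold), followed by the cyclin gene Ccne2 (-2.03), the pocket protein gene Rbl1 (-1.83) and the chemokine receptor gene Cxcr4 (-1.79). The platelet-derived growth factor receptor gene Pdgfrb (-2.03) and the membrane protein gene Ms4a6b (-1.71) fell too. Mef2d rose modestly (0.65, SE 0.09, adjusted p = 2.5e-05). Hdac7 fell by 0.35 (adjusted p = 0.0419), a call that ended on series 14 slides alone (-0.02). In all 2057 probes were called, 999 higher and 1058 lower, 343 of them at least 2-fold (191 higher), and 2151 with the sign of both unsettled arrays turned (1786 shared).

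Of 32 immediate early genes 23 rose with PMA and ionomycin, 2 fell and 7 were not called (camera adjusted p = 6.75e-22), and of 36 activation and cytokine genes 22 rose and 0 fell (camera adjusted p = 6.75e-22). Apoptosis genes rose as well: 9 of 27, with 3 lower (camera adjusted p = 0.0104 and adjusted p = 0.0898 with an estimated correlation), and Fasl, Gadd45b and Gadd45g (1.61) were among those that rose. Cell cycle genes fell: 9 of 35, with 0 higher (15 over the list alone, camera adjusted p = 2e-06 and adjusted p = 0.165 with an estimated correlation), including the spindle checkpoint kinases Bub1 (-1.21) and Ttk (-1.16) and the thymidine kinase gene Tk1 (-1.14). Heat shock and stress genes tended down, with 1 of 17 higher and 4 lower (camera adjusted p = 0.0387 and adjusted p = 0.113 with an estimated correlation), Trib3 and Ddit3 (-1.06) lowest and the chaperone gene Hspa8 (0.82) higher. The list of lymphocyte migration genes was split, 4 of 17 up and 2 down, with the chemokine receptor gene Cxcr3 (2.34) highest and Cxcr4 lowest. With slides of one set averaged, 535 probes were called (525 shared).

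HDAC7 DP lowered part of this response. Against stimulated empty-virus cells (8 arrays each), Nr4a1 fell 5.32-fold (-2.41, SE 0.45, adjusted p = 0.00939), Irf4 5.21-fold (-2.38, SE 0.28, adjusted p = 0.000164), Pdcd1 5.05-fold (-2.34, SE 0.27, adjusted p = 0.000118) and Cd28 3.12-fold (-1.64, SE 0.14, adjusted p = 7.11e-06). The phosphatase gene Dusp2 (5.47-fold), Hdac5 (4.22-fold), Lef1 (4.18-fold), Nab2 (3.78-fold) and the synaptic activity gene Arc (3.72-fold) were lower as well. So were the lymphotoxin genes Lta and Ltb (both -1.59), the T cell receptor signalling kinase gene Zap70 (-1.18) and Cd24a (-1.13). Gadd45b (-1.12), Cd6 (-1.11) and the CD4-lineage factor gene Zbtb7b (-0.74) were lower too. On every HDAC7 DP array Irf4, Pdcd1 and Cd28 lay below their lowest value on the stimulated empty-virus arrays (0.91 at most against 2.02 at least for Pdcd1). For Nr4a1 the ranges met (at most 3.30 against at least 3.09). The receptor kinase gene Mst1r (3.21-fold), the metalloprotease gene Adam8 (2.77-fold), the ectonucleotidase gene Nt5e (2.67-fold) and the hexokinase gene Hk2 (1.11) rose. Of 271 called probes 86 were higher and 185 lower, and of the 59 that changed at least 2-fold 9 were higher and 50 lower. Hdac7 RNA was 2.31 higher but not called (SE 0.69, adjusted p = 0.127), since it stood at 4.00 (SD 0.59) over untreated cells on the 4 arrays of slide series 15 and at 0.17 (SD 0.21) on the 4 of series 14. In series 15 alone it rose (4.45, adjusted p = 0.00116). Mef2d was level (0.04).

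Stimulation was not abolished by HDAC7 DP. Against untreated cells Nr4a1 was still raised, to a mean of 2.80 on slides 17 and 18 and 0.97 on slides 19 and 20, beside 3.67 on slides 13 and 14 and 4.92 on slides 15 and 16 of the empty virus. Il2 reached 4.20 and 1.79 with HDAC7 DP and 1.83 and 4.87 with the empty virus. The sets of slides within a construct thus differed more than the constructs, and Il2 did not separate the constructs. Pdcd1 did: 0.53 and -0.11 with HDAC7 DP, 2.25 and 2.85 without. Of 32 immediate early genes 7 fell and 0 rose (camera adjusted p = 1.24e-05 and adjusted p = 0.451 with an estimated correlation). In the list of T cell activation and cytokine genes 5 of 36 fell and 0 rose (camera adjusted p = 1.24e-05 and adjusted p = 0.451 with an estimated correlation). Of 24 T cell receptor signalling genes 3 fell, Cd28, Zap70 and Cd6, and 0 rose (camera adjusted p = 0.00224 and adjusted p = 0.338 with an estimated correlation). When slides of one set were averaged before the limma fit, 0 probes passed (622 at an unadjusted p under 0.05). The folds were unchanged, but only 4 averaged values remained. Their spread also held the difference between slides 13, 14, 19 and 20 and slides 15 to 18, a split that called 3312 probes. A fit with that split as a block was not run. Within slide series 14 alone 192 probes were called (20 higher, 172 lower, 85 shared), and Irf4 (-2.56), Pdcd1 (-2.18) and Cd28 (-1.75) fell. The Hdac7 probe was not raised there, though slides 17 to 20 bear the same numbers in both series. Whether the probe or the RNA differed between series was not tested, so its level does not show that HDAC7 DP was absent. Within slide series 15 alone 27 were called (22 shared), and Nr4a1 (-2.01), Irf4 (-2.21) and Pdcd1 (-2.50) no longer passed, while in series 14 Nr4a1 (-2.81) did not.

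**Figure D1:**
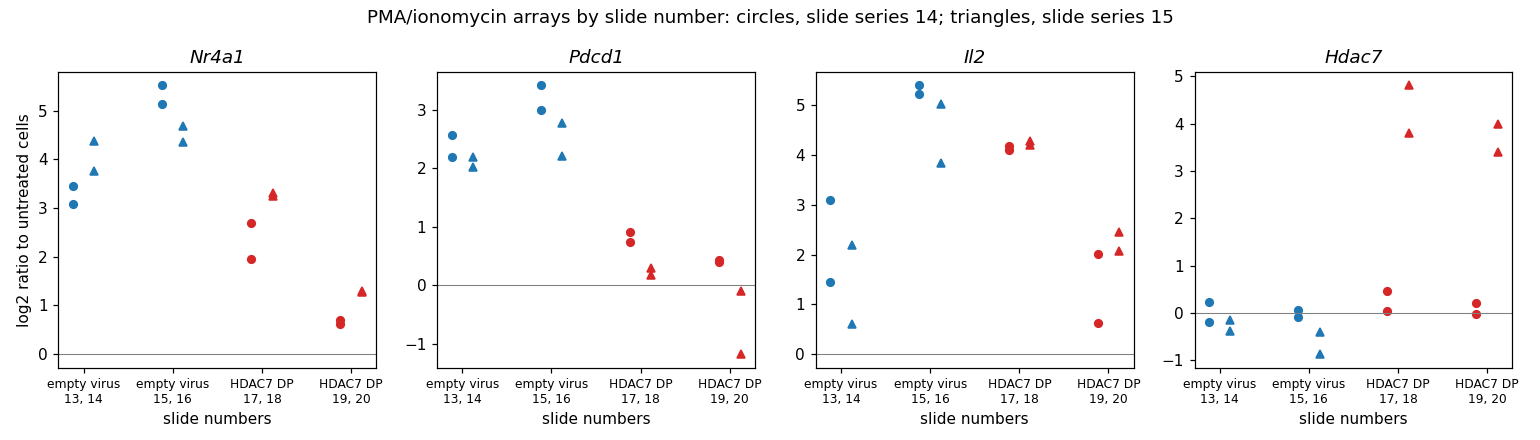
Log2 ratio to untreated cells of Nr4a1, Pdcd1, Il2 and Hdac7 on each stimulated array, by construct and slide number. Circles are slide series 14 and triangles slide series 15.

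Nur77, delivered by the virus, was itself 20.6-fold higher (Nr4a1 4.36, SE 0.47, adjusted p = 0.000296; 4 of 4 arrays). It raised an unusual group of genes: the serum glycoprotein gene Ahsg 71.4-fold (6.16, SE 0.30), the vesicle fusion gene Napb 36.8-fold (5.20, SE 0.16), the neuronal calcium-binding gene Necab2 33.2-fold (5.05, SE 0.25) and the alkaline phosphatase gene Alpl 21.1-fold (4.40, SE 0.31). Immune cell genes followed: Cd28 10.3-fold (3.37, SE 0.21), Bcl6 8.05-fold, the myeloid integrin gene Itgam 7.44-fold, Pdcd1 6.43-fold (2.69, SE 0.13) and the TRAIL gene Tnfsf10, a death ligand, 4.94-fold. Cd6 (1.91), Cd5 (1.26), the apoptosis-linked kinase gene Stk17b (1.16) and Dntt, the gene of terminal transferase (0.88), rose too. Igfbp4, which binds insulin-like growth factors, fell 11.8-fold (-3.56, SE 0.18), Ms4a6b 6-fold (-2.58, SE 0.13) and the surface antigen gene Ly6c1 by 1.82. Egr1 fell by 1.42, Bcl2 by 0.99, the integrin gene Itgal by 0.97 and the activation antigen Cd69 by 0.81. With all 16 empty-virus arrays as control 11 of 44 called named genes lost their call, Ly6c1 (-0.85), Bcl2 (-0.15), Itgal (-0.52) and Cd69 (-0.49) among them. Against untreated cells Ly6c1 stood at -0.70 and Bcl2 at -0.30 (not called), so these falls owe part of their size to MSCV_B. Of 1138 called probes 596 were higher and 542 lower, and of 284 that changed at least 2-fold 212 were higher. Without MSCV_B replicate 1 the count was 677 and without MSCV_B replicate 3 it was 695. It was 365 without a dye term and 603 with all groups in one fit. Hdac7 was 0.69 lower (adjusted p = 0.0482), and this call ended without any 1 of the 8 arrays (-0.78 to -0.52). Since Hdac7 was lower in MSCV_B too, it stood at -1.52 (adjusted p = 0.00087) against untreated cells and at -1.41 (adjusted p = 0.000529) with all 16 empty-virus arrays as control.

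No list followed Nur77 as a whole over MSCV_B. Against untreated cells cholesterol synthesis genes, which had fallen in MSCV_B too, fell in 7 of 14 and rose in 0 (camera adjusted p = 1.37e-05). Glucocorticoid-response genes fell there in 5 of 12 and rose in 1 (camera adjusted p = 0.00254). Both calls ended with an estimated correlation (camera adjusted p = 0.585). The counts that follow are over MSCV_B. Of 36 activation and cytokine genes 4 rose and 3 fell (camera adjusted p = 0.9), of 31 mature single-positive thymocyte genes 5 rose and 7 fell (10 and 8 over the list alone, camera adjusted p = 0.91), and of 32 immediate early genes 4 rose and 6 fell (camera adjusted p = 0.9). Of 20 double-positive thymocyte genes 4 rose, Bcl6 and Dntt among them, and 1 fell, Lef1 (-0.88), whose call ended without any 1 of MSCV_B replicates 1, 3 and 4 and Nur77 replicates 2, 3 and 4 (-1.11 to -0.70 over all 8 fits), as well as against untreated cells (-0.43) and with all 16 empty-virus arrays as control (-0.29). Of 27 apoptosis genes 2 rose, Tnfsf10 and Stk17b, and 2 fell.

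MEF2D-VP16 changed more probes than any other construct set against an empty virus. Of 2067 called probes 1053 were higher and 1014 lower, 522 of them at least 2-fold (293 higher; 4 arrays against 4). Selenbp2 rose 40.3-fold (5.33, SE 0.16; 1.95 against untreated cells, since it had fallen in MSCV_B, and not called with all 16 empty-virus arrays as control), Ahsg 23.5-fold (4.55, SE 0.17), Eno3 14.6-fold and Cd28 14-fold (3.81, SE 0.25; 4 of 4 arrays). The class IIa deacetylase genes Hdac5 (8.71-fold; 3.12, SE 0.14, adjusted p = 3.01e-06) and Hdac7 (4.58-fold; 2.19, SE 0.16, adjusted p = 6.74e-05) rose. Pdcd1 rose 6.03-fold (2.59, SE 0.11) and Nr4a1 2.34-fold (1.23, SE 0.19, adjusted p = 0.00264; 1.85 with all 16 empty-virus arrays as control). The quiescence factor gene Klf2 (2.47), the circadian repressor gene Bhlhe40 (2.08), Cd6 (1.88), the Notch target Hes1 (1.85) and Gadd45b (1.76) rose. The costimulatory ligand gene Tnfsf4 fell 6.83-fold (-2.77, SE 0.22), with the p53 targets Phlda3 (-2.77) and Aen (-2.14), Ms4a6b (-2.67), the inhibitory Fc receptor gene Fcgr2b (-2.25) and the kinase gene Sgk1 (-2.02, SE 0.17). Many of these sizes rest on MSCV_B as control. With all 16 empty-virus arrays 22 of 60 called named genes lost their call, Klf2 (1.28), Bhlhe40 (0.59), Gadd45b (0.88) and Aen (-1.03) among them. Against untreated cells Hdac7 stood at 1.36, Bhlhe40 at 0.68, Gadd45b at 1.11, Hes1 at 1.20, Tnfsf4 at -1.25, Phlda3 at -1.58 and Sgk1 at -1.29, all called. Mef2d's own probe was level (-0.04), so it gave no measure of the construct. Without 1 array the count ran from 1406 to 1860, and 52 of 60 called named genes kept their call in every such fit.

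Cell cycle genes tended down with MEF2D-VP16. Of 35 measured, 16 fell, 0 rose and 19 were not called (19 fell over the list alone, camera adjusted p = 1.77e-10 and adjusted p = 0.163 with an estimated correlation). The helicase subunit gene Mcm5 fell 2.79-fold (-1.48, SE 0.11), the loading factor gene Cdc6 by 1.59 and the cyclin gene Ccne1 by 1.68. Cholesterol synthesis genes rose: 6 of 14, with 0 lower (9 and 1 over the list alone, camera adjusted p = 0.000444 and adjusted p = 0.163 with an estimated correlation), among them the lipid transfer gene Stard4 (1.10) and the mevalonate pathway genes Fdps (0.92) and Mvd (0.86). This list had fallen in the MSCV_B control (median -0.57), and with MEF2D-VP16 against untreated cells it was not called (2 of 14 higher, 1 lower, median -0.03, camera adjusted p = 0.92), where Fdps (0.22) and Mvd (0.23) lost their call and Stard4 stood at 0.35. Ccne1 stood at -1.04 there. Immediate early genes rose in 9 of 32 and fell in 1 (camera adjusted p = 0.00151 and adjusted p = 0.163 with an estimated correlation), led by Bhlhe40, the stress gene Ier3 (1.89; 1.18 against untreated cells and 0.94 with all 16 empty-virus arrays as control) and Gadd45b. Mature single-positive genes rose in 11 of 31 and fell in 4 (camera adjusted p = 0.0114 and adjusted p = 0.2 with an estimated correlation), Klf2 highest and Ms4a6b lowest. Of 12 HDAC and MEF2 genes 3 rose, Hdac5, Hdac7 and Mef2b (0.56), and 0 fell (camera adjusted p = 0.112). The Mef2b call ended without MEF2D_VP16 replicate 2, MSCV_B replicate 2 or MSCV_B replicate 4 (0.49 to 0.66 over all 8 fits), and against untreated cells (0.19). Of 25 interferon-response genes 2 rose and 6 fell, with Ifit1 (-1.11) among the latter (camera adjusted p = 0.55). Ifit1 was not called against untreated cells (-0.059) or with all 16 empty-virus arrays as control (-0.36).

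**Figure D2:**
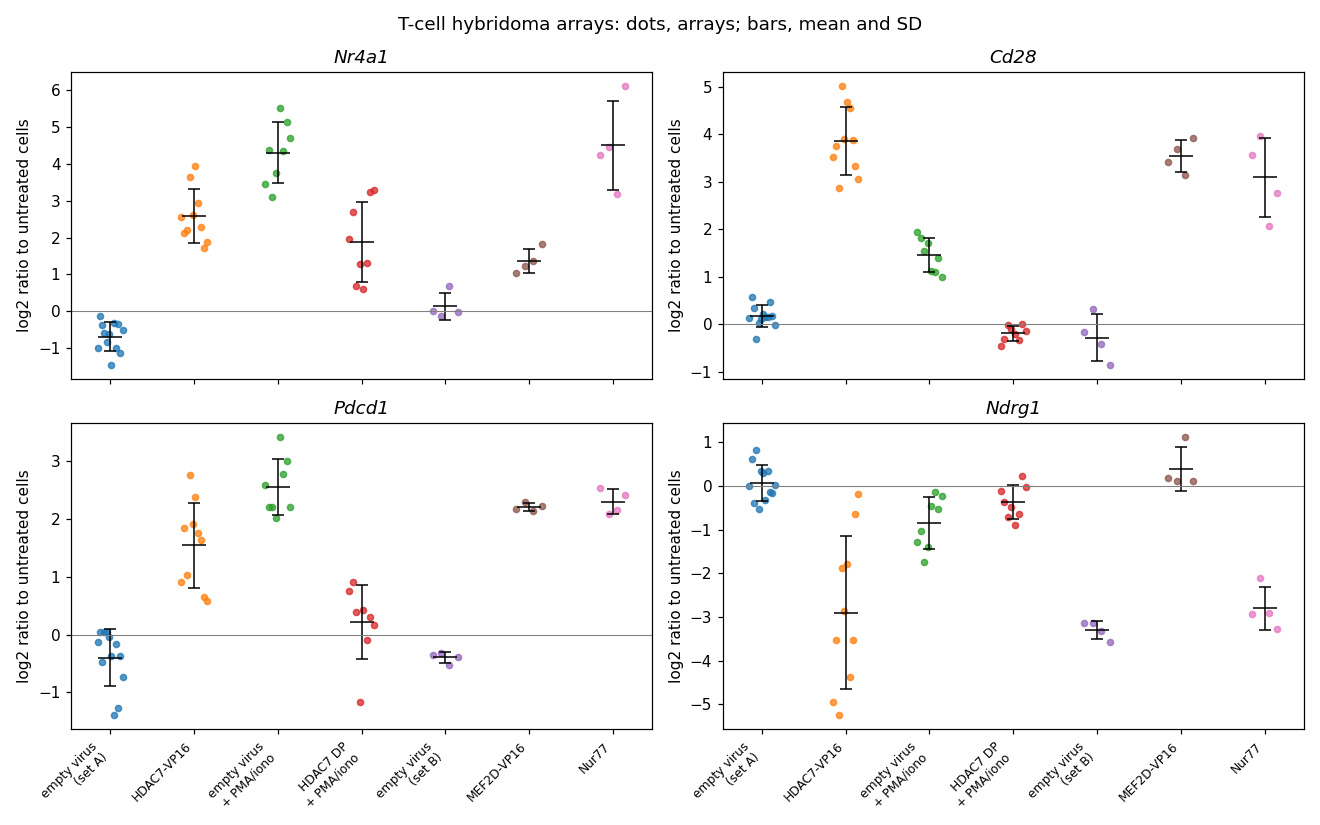
Log2 ratio to untreated hybridoma cells of Nr4a1, Cd28, Pdcd1 and Ndrg1 in the 7 hybridoma groups. Dots are arrays and bars give mean and SD.

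Across probes, the 16 relations between comparisons rest on genes that are not independent replicates. Changes made by HDAC7-VP16 and by HDAC7 DP ran opposite (r = -0.201, and -0.35 over the 660 probes called in either). Here 39 probes were higher with HDAC7-VP16 and lower with HDAC7 DP where independence gives 2.63, with Nr4a1, Cd28, Pdcd1, Irf4, Hdac5, Lef1 and Cd6 among them. HDAC7-VP16 and Nur77 shared 65 higher probes (expected 8.47; r = 0.132), Cd28, Pdcd1, Cd5 and Cd6 among them. HDAC7-VP16 and MEF2D-VP16 correlated little (r = -0.0841). They shared 78 higher probes (expected 15), Cd28, Pdcd1, Nr4a1 and Hdac5 among them, but 80 were lower with HDAC7-VP16 and higher with MEF2D-VP16 (expected 13.6), Ndrg1, Selenbp2 and Trib3 among them. How far these 3 rose with MEF2D-VP16 depended on MSCV_B as control. Against untreated cells they stood at 0.38, 1.95 and 0.044, and with all 16 empty-virus arrays as control none of the 3 was called (1.15, 2.43 and -0.067). Over MSCV_B, which both used as control, MEF2D-VP16 and Nur77 correlated at 0.327, where simulated unchanged groups gave 0.494, so the correlation alone shows no relation. The covariance was 0.0479 against 0.0175 simulated, and with the controls split the correlation was 0.234. They shared 198 higher probes (expected 38.1 if independent), and with the controls split 48 and 61 (expected 4.92 and 6.83). The control arrays were also shared between HDAC7-VP16 and PMA with ionomycin (r = 0.363 against 0.429 simulated, covariance 0.0284 against 0.0115 simulated, r = 0.213 with the controls split). HDAC7 DP and stimulation share the stimulated empty-virus arrays with opposite sign and correlated at -0.38, no further from 0 than the -0.546 simulated (covariance -0.0331 against -0.0153 simulated, r = -0.216 with the shared arrays split). Of the stimulated probes 71 were lower with HDAC7 DP (expected 11.2 if independent), and with the shared arrays split 29 and 28 were (expected 2.6 and 2.97). Simulated unchanged groups had no overlapping calls and set no benchmark for these overlaps. In thymocytes, changes of HDAC7-VP16 correlated with the MHC comparison at 0.179, read as DO11.10 over mhc -/-. That direction is only likely, and the sign rests on it. With peptide these changes correlated at 0.0368 (3 h), 0.0421 (6 h) and -0.0875 (12 h). Those of Nur77 correlated with peptide at 0.0227, 0.0245 and 0.134, and those of PMA with ionomycin at 0.165, 0.195 and 0.0103. Stimulation and peptide shared 86, 100 and 59 higher probes at these times (expected 14.9, 20.3 and 16.6), Nr4a1, Irf4 and Gadd45b among them.

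The comparison of DO11.10 with mhc -/- thymocytes likely runs as DO11.10 over mhc -/-, opposite to the order assumed beforehand, because B2m and class II genes were high. B2m, the gene of the MHC class I light chain, was 9.57-fold higher (3.26, SE 0.10, adjusted p = 1.3e-06; 6 of 6 arrays), and the class II genes H2-Ab1 (2.42), H2-Eb1 (2.37) and H2-Aa (1.96) went with it. H2-D1 was level (0.11, adjusted p = 0.45) and stood at -0.80 with its probes averaged. Other class I genes went the other way, with H2-Bl 10.3-fold lower (-3.36, SE 0.11) and H2-T23 (-1.71) and H2-Q8 (-1.33) lower, so not every MHC gene supports this reading. Read that way, some genes induced by the T cell receptor were higher in DO11.10 thymocytes. The lists of immediate early genes (13 of 32 up, 8 down, camera adjusted p = 0.243) and of activation and cytokine genes (14 of 36 up, 7 down, camera adjusted p = 0.19) were not called, however. Because the labels name total thymocytes, a difference in RNA per cell and one in cell composition cannot be told apart. Nr4a1 was 3.71-fold higher (1.89, SE 0.07, adjusted p = 2.62e-06; 6 of 6 arrays), Egr1 8.95-fold (3.16, SE 0.08), Cd5, which tracks receptor signal strength, 13.6-fold (3.77, SE 0.21), Cd69 4.37-fold (2.13, SE 0.06), Bcl6 3.28, Lef1 2.32 and Hdac5 4.75-fold (2.25, SE 0.14). The aspartic protease gene Ctse had the highest value (21.5-fold), followed by the chromatin gene Supt16 (3.94), the class II gene H2-Ea (3.91), Xist (14.1-fold) and the lipid synthesis gene Acly (3.72). The peptide transporter gene Slc15a2 (18-fold; -4.17, SE 0.13), the replication factor gene Pclaf (14.8-fold), the GTPase effector gene Arl2bp (-3.77) and the decay helicase gene Upf1 (-3.46) were among the lowest. Ly6d (-3.10), a lymphoid progenitor antigen, the aquaporin gene Aqp11 (-2.80) and the cell cycle inhibitor gene Cdkn1a (-1.64) were lower too. Hdac7 was 0.46 higher (adjusted p = 0.0243), a call that ended without any 1 of replicates 1 to 5 (0.38 to 0.48). Mef2d (0.20, adjusted p = 0.0601) was not called.

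With 5975 called probes (3372 higher, 2603 lower) this comparison was by far the broadest, and 1219 changed at least 2-fold (1009 higher). Mature single-positive thymocyte genes were higher in 20 of 31 and lower in 4 (camera adjusted p = 1.96e-06 and adjusted p = 0.0707 with an estimated correlation), with Cd5, the GTPase gene Gimap4 (3.21) and Itgb7 (2.15). T cell receptor signalling genes were higher in 18 of 24 and lower in 1 (camera adjusted p = 9.88e-06 and adjusted p = 0.326 with an estimated correlation), with the phosphatase gene Ptpn6 (2.57) and the exchange factor gene Vav1 (2.48). Migration genes were higher in 11 of 17 and lower in 4 (camera adjusted p = 0.0035 and adjusted p = 0.326 with an estimated correlation), with Cxcr4 (2.58) and the selectin ligand gene Selplg (2.29). Cell cycle genes went down in 19 of 35 and up in 6 (camera adjusted p = 0.0035 and adjusted p = 0.162 with an estimated correlation), though Mcm2 (2.14) and Plk1 (1.13) were higher. Stroma and epithelium genes were higher in 10 of 16 and lower in 2 (camera adjusted p = 0.0104 and adjusted p = 0.385 with an estimated correlation), with the platelet adhesion gene Pecam1 and the chemokine gene Ccl25 (1.55) up and Epcam (-1.20) down. Other lists not called by camera included MHC class II and presentation (5 of 11 up, 1 down, adjusted p = 0.101), early double-negative thymocytes (4 of 14 up, 3 down, adjusted p = 0.66), B cells (4 of 11 up, 3 down, adjusted p = 0.719), myeloid cells (2 of 14 up, 7 down, adjusted p = 0.106) and erythroid cells (2 of 4 up, adjusted p = 0.106). Probes of the same gene disagreed often here: of 197 genes with several called probes, 70 had probes called in both directions, the apoptosome gene Apaf1 (1.54) among them.

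Peptide injection raised a compact set of receptor-induced genes within 3 h. Gadd45b rose 11.2-fold (3.49, SE 0.21, adjusted p = 0.000389; 6 of 6 arrays), Nr4a1 8.37-fold (3.06, SE 0.09, adjusted p = 2.89e-05; 6 of 6), Irf4 7.36-fold (2.88, SE 0.13), the chemokine gene Ccl22 7.04-fold (2.81, SE 0.09), Cd69 5.76-fold (2.53, SE 0.15) and the OX40 gene Tnfrsf4 5.53-fold (2.47, SE 0.08). The vesicle gene Stx11 (2.00), Bhlhe40 (2.00), Tnf (1.66), Cd5 (1.53) and Cd6 (1.07) rose. Bcl2l11, the gene of the death inducer BIM, rose 2.34-fold (1.23, SE 0.09, adjusted p = 0.00101). The largest falls of called genes with a symbol were in the thymus serine protease gene Prss16 (3.95-fold; -1.98, SE 0.10), the chemokine gene Ccl25 (-1.55), the growth-arrest ligand gene Gas6 (-1.53) and the heme synthesis gene Alas2 (-1.32). The thymoproteasome gene Psmb11 (-1.16) and the keratin gene Krt8 (-0.99) fell too. Of 446 called probes 246 were higher and 200 lower, and of 64 that changed at least 2-fold 55 were higher. Both the count and its balance depended on the setting: 1447 probes (590 higher, 857 lower) without slides 13-3 and 13-4, 1721 (727 higher, 994 lower) with array weights and 724 (425 higher, 299 lower) with all groups in one fit. The count fell to 152, 155, 100 and 124 without replicates 3, 4, 5 and 6, each left out alone, and 25 of 39 called named genes kept their call in every fit without 1 array. Hdac7 was 0.37 lower (adjusted p = 0.243) and Mef2d 0.30 lower, and neither was called.

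At 6 h Nr4a1 was as high (8.25-fold; 3.04, SE 0.07) and Ccl22 higher (11.5-fold; 3.53, SE 0.10), and the interferon-inducible GTPase genes Tgtp1 (9.52-fold; 3.25, SE 0.11) and Gbp2 (3.72-fold; 1.90, SE 0.07), already called at 3 h (1.20 and 0.58), stood higher, with Gbp3 at 1.61. Gadd45b (3.19) and Tnfrsf4 (3.00) remained high, and the basement membrane gene Lad1 (2.57), the receptor genes Tnfrsf19 (2.25) and Tnfrsf18 (1.55), Irf4 (2.16), the noncanonical NF-kB gene Nfkb2 (1.65) and Irf1 (1.61) rose. Prss16 (-1.84), Psmb11 (-1.73), Gas6 (-1.45), Ccl25 (-1.41) and the thymic epithelial factor gene Pax1 (-1.11) fell. The recombinase gene Rag2 (-0.51), the double-positive transcription factor gene Lef1 (-0.49) and Notch1 (-0.62) fell as well, though these calls ended without single arrays (Rag2 and Notch1 without any 1 of replicates 3 to 6, Lef1 without any 1 of replicates 2 to 6; -0.57 to -0.42, -0.74 to -0.53 and -0.61 to -0.42 over all 6 fits). Hdac7 fell by 0.39 (SE 0.07, adjusted p = 0.0267), a call that ended without any 1 of replicates 2 to 6 (-0.41 to -0.32). Of 753 called probes 335 were higher and 418 lower, 84 of them at least 2-fold (69 higher). Without replicates 3, 4, 5 and 6, each left out alone, the count was 320, 388, 279 and 334. It rose to 1906 (732 higher, 1174 lower) without replicates 1 and 2 and to 2022 (829 higher, 1193 lower) with array weights.

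After 12 h Tnfrsf4 (8.46-fold; 3.08, SE 0.09; 6 of 6 arrays) and Ccl22 (3.04, SE 0.11) held, and interferon-linked genes were at the top: Tgtp1 (9.16-fold; 3.19, SE 0.36; not called without any 1 of replicates 4 to 6, 2.77 to 3.44 over all 6 fits), the receptor transporter gene Rtp4 (2.44) and Ifi27l2a (2.39, SE 0.13). The metallothionein gene Mt2 (2.27), Bhlhe40 (2.26), Gbp2 (1.95, SE 0.18), B2m (1.25) and the anti-apoptotic gene Birc3 (1.06) rose, and Runx3, the CD8-lineage factor gene, rose by 1.21. Nr4a1 was 3.37-fold higher (1.75, SE 0.31, adjusted p = 0.0402), but the call ended without any 1 of replicates 3 to 6 (1.81 to 2.00), and it stood at 2.77 on replicates 1 and 2 against 1.25 on the other 4. Prss16 (-1.96, SE 0.09) and Stmn1, the gene of a microtubule regulator (-1.35), fell. Cxcr4 (-2.09), the guidance receptor gene Plxnd1 (-1.84), Notch1 (-1.19), the adaptor gene Lat (-1.06) and Hdac7 (-0.57, adjusted p = 0.0447) fell too, each losing its call without any 1 of replicates 3 to 6 (-2.51 to -1.82, -2.15 to -1.67, -1.31 to -1.13, -1.21 to -0.92 and -0.68 to -0.51 over all 6 fits). Of 557 called probes 274 were higher and 283 lower, 139 of them at least 2-fold (93 higher). Each left out alone, replicates 1 and 2 raised the count to 1832 and 1629 and replicates 3 to 6 lowered it to 69, 94, 46 and 61, and 15 of 43 called named genes kept their call in every fit without 1 array. Replicates 1 and 2 stood apart. Without both, 4067 probes were called (1394 higher, 2673 lower), including all 557. Array weights gave 3849 (1333 higher, 2516 lower) and all groups in one fit 3424 (1272 higher, 2152 lower).

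**Figure D3:**
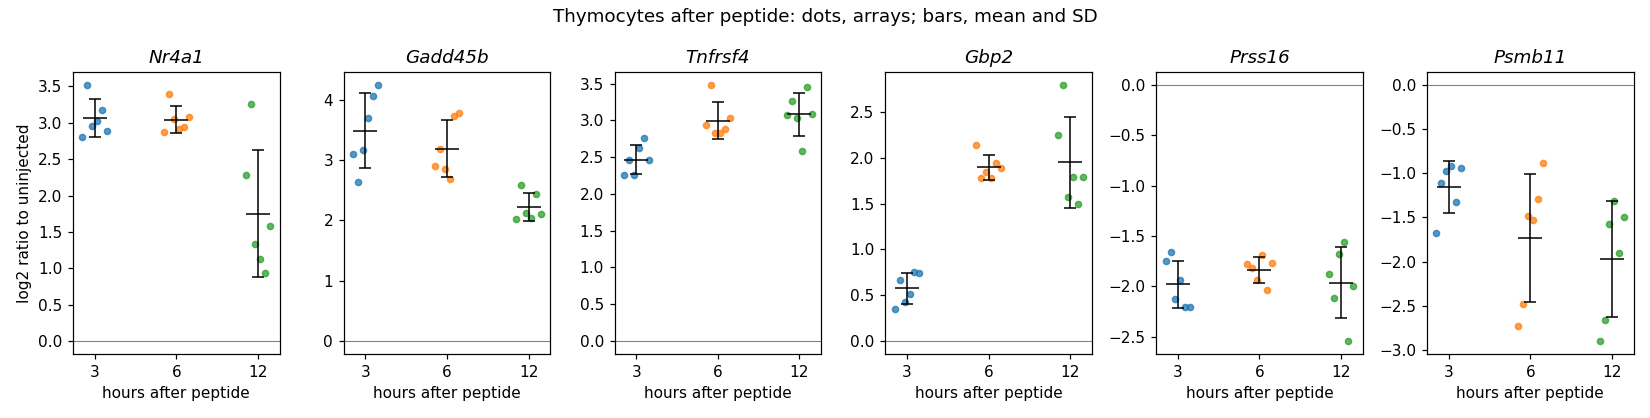
Log2 ratio to uninjected thymocytes of Nr4a1, Gadd45b, Tnfrsf4, Gbp2, Prss16 and Psmb11 at 3 h, 6 h and 12 h after peptide. Dots are arrays and bars give mean and SD.

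Lists of activation genes and of interferon genes rose at all 3 times. Immediate early genes rose in 16, 16 and 9 of 32 at 3 h, 6 h and 12 h and fell in 0 (camera adjusted p = 2.04e-21, 3.39e-22 and 8.07e-09; at 12 h adjusted p = 0.181 with an estimated correlation). Activation and cytokine genes rose in 14, 18 and 10 of 36, with 1 lower at 12 h (camera adjusted p = 1.72e-21, 7.54e-21 and 3.19e-08; adjusted p = 0.0696 and 0.232 with an estimated correlation at 6 h and 12 h). Apoptosis genes rose in 5, 4 and 6 of 27, with 1 lower at 6 h (camera adjusted p = 9.4e-05, 9.97e-05 and 0.00139; adjusted p = 0.0696 and 0.111 with an estimated correlation at 6 h and 12 h), with Gadd45b, Bcl2l11, the inhibitor gene Cdkn1a (1.24 at 3 h) and Birc3 as examples. Interferon-response genes rose in 5, 15 and 7 of 25 and fell in 0 (7, 17 and 15 over the list alone, camera adjusted p = 0.000165, 1.3e-20 and 5.23e-10; adjusted p = 0.0714 and 0.336 with an estimated correlation at 3 h and 12 h). Double-positive thymocyte genes fell in 4, 4 and 1 of 20 (11, 11 and 10 over the list alone, camera adjusted p = 8.94e-08, 1.83e-07 and 0.000135; adjusted p = 0.0585 and 0.104 with an estimated correlation at 3 h and 12 h). Cell cycle genes fell in 1, 3 and 6 of 35, and in 9 and 19 over the list alone at 6 h and 12 h (camera adjusted p = 1.08e-05 and 2e-10 and adjusted p = 0.3 with an estimated correlation at 6 h), Cdc6 and Plk1 among them. The calls of Cdc6 (-1.14) and Plk1 (-1.01) at 12 h ended without any 1 of replicates 3 to 6 (-1.30 to -1.0 and -1.15 to -0.90 over all 6 fits). Stroma and epithelium genes fell in 5, 6 and 2 of 16 (camera adjusted p = 1.21e-09, 6.09e-09 and 0.782), with Ccl25 and Psmb11. Myeloid genes fell in 3, 6 and 2 of 14 (camera adjusted p = 1.89e-05, 1.96e-06 and 0.531 and adjusted p = 0.0714 with an estimated correlation at 3 h), erythroid genes in 2, 2 and 1 of 4 (camera adjusted p = 4.75e-05, 8.98e-05 and 0.0222; adjusted p = 0.0886, 0.14 and 0.324 with an estimated correlation). Without replicates 1 and 2, which for lists was chosen after the data were seen, interferon genes rose in 5, 16 and 14 and fell in 0, 1 and 4, activation and cytokine genes rose in 17, 19 and 18 and fell in 0, 0 and 6, and cell cycle genes fell in 3, 15 and 21 and rose in 0, 1 and 1. In these fits of 4 arrays no list was called with an estimated correlation at any time (lowest adjusted p = 0.175, 0.122 and 0.242), immediate early, double-positive and stroma genes included. The 3 times differed in 674 probes (limma F test). In a separate contrast of 12 h with 3 h, 276 probes were higher and 526 lower. Ifi27l2a (2.38 apart), Tgtp1 (1.99) and Rtp4 (1.96) gained most among interferon genes, while Bcl6 (-1.88), the nucleolar gene Nolc1 (-1.98) and the cyclin-dependent kinase gene Cdk4 (-1.74) lost most. The count of differing probes was 1615, 1570, 347, 356, 271 and 271 without 12 h replicates 1 to 6, each left out alone, and 446, 447 and 449 without 6 h replicates 3, 5 and 6. It was 1421 with slide series 13 as a block and 2749 between 6 h and 12 h without that series.

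Both empty-virus groups differed from untreated cells, though not in the same way. MSCV_A called 325 probes over 12 arrays, 103 higher and 222 lower, 0 of them by 2-fold or more (1968 at an unadjusted p under 0.05 by limma). The cyclin gene Ccng2 rose 1.77-fold (0.82, SE 0.06, adjusted p = 7.21e-05; 12 of 12 arrays), with the mitochondrial carrier gene Slc25a13 (0.77), the cytoskeletal effector gene Cdc42ep2 (0.75) and Klf2 (0.88). Nr4a1 fell 1.61-fold (-0.69, SE 0.11, adjusted p = 0.006), the splicing-linked gene Rsrp1 by 0.90 and the tetraspanin gene Cd53 by 0.71. Immediate early genes rose in 5 of 32 and fell in 1 (camera adjusted p = 0.00515 and adjusted p = 0.0663 with an estimated correlation), mature single-positive genes rose in 1 of 31 and fell in 5 (10 over the list alone, camera adjusted p = 0.00515). With the sign of both unsettled arrays turned, limma called 0 probes (1376 unadjusted), and Nr4a1 (-0.46) lost its call. With the dye of both exchanged instead, 623 were called (320 shared). After removal of the dye effect these 2 arrays correlated with the others at 0.182 and 0.28, which speaks more for exchanged dyes than for a turned sign, but the count depends on how they are read. Series 14 alone called 41 probes and series 15 alone 189.

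The 4 arrays of MSCV_B called 942 probes, 446 higher and 496 lower, 44 at least 2-fold (20 in all without a dye term, 362 with all groups in one fit). Selenbp2 fell 10.4-fold (-3.38, SE 0.11), Ndrg1 9.8-fold (-3.29, SE 0.08, adjusted p = 3.42e-06; 4 of 4 arrays), Bnip3 5.3-fold (-2.41, SE 0.07), the glycolytic gene Aldoc by 2.31 and Ccng2 by 2.23. Gm20767 (3.79-fold), Tnfsf4 (2.87-fold), the thiamine transporter gene Slc19a2 (1.19) and the p53 targets Phlda3 (1.19) and Aen (1.16) rose. Hdac7 fell 1.78-fold (-0.83, SE 0.11, adjusted p = 0.00653). Cholesterol synthesis genes fell in 10 of 14 and rose in 0 (camera adjusted p = 1.97e-10 and adjusted p = 0.353 with an estimated correlation), with Fdft1 (-0.83), Lss (-0.78) and Msmo1 (-0.78) lowest. Without replicates 1 to 4, each left out alone, 397, 448, 347 and 390 probes were called, and 37 of 54 called named genes kept their call in every such fit. Selenbp2, Ndrg1, Ccng2, Tnfsf4, Phlda3 and Aen moved the other way with MEF2D-VP16, whose fit subtracts MSCV_B, and there Ndrg1 stood at 0.38 against untreated cells.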

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

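The tests of dye bias and RNA quality in the MHC comparison and the comparison of both empty-virus groups were chosen only after the result was seen. Hypoxia-linked genes made a pattern that no comparison was built for. A list of 24 hypoxia-induced genes, written before its members were looked at (19 measured), fell in 11 genes with MSCV_B (median -0.558) and in 6 with HDAC7-VP16 (median -0.343), and rose in 13 and fell in 1 with MEF2D-VP16 (median 0.904). It held 1 higher gene with MSCV_A (median 0.0698) and 0 called genes with Nur77 over MSCV_B (median -0.031). With PMA and ionomycin 8 genes fell and 2 rose (median -0.159), so the pattern was not confined to these constructs. In the MHC comparison 6 were lower and 3 higher (median -0.0547). That says little, since 2603 of all 16463 probes were lower there and 3372 higher. The glucose transporter gene Slc2a1 stood at -1.0 with MSCV_B, -1.31 with HDAC7-VP16 and 1.78 with MEF2D-VP16, the glycogen synthase gene Gys1 at -1.20, -1.15 and 2.05, and the mitophagy gene Bnip3l at -0.99, -1.0 and 1.67. The MSCV_B control alone carrying the rise with MEF2D-VP16 was argued against by the median of 0.342 against untreated cells, where 9 genes rose. An untreated reference that differed between hybridisation sets remains possible, since Nur77 against the same reference had a median of -0.302 with 7 genes lower. An effect of HDAC7-VP16 shared by its slide sets remains possible as well, since the medians were -0.34, -0.521 and -0.503 and none came near 0. Oxygen, cell density and harvest are not given in the sources used here, so the pattern may be a matter of culture.

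Xist, the RNA that coats the silenced X chromosome, was 14.1-fold higher on the MHC arrays, and probes of the same gene disagreed there more than elsewhere. The Y-linked genes went with a difference in the sex of the thymocyte donors. Kdm5d (-1.25), Uty (-1.41) and Eif2s3y (-1.90) were all called lower (3 of 3 measured; median -1.4). Dye bias was argued against, because the means of Cy5 and Cy3 arrays correlated at 0.938 over all probes. The first and second probe of a gene correlated at 0.0502 here and at 0.0797 to 0.556 in the other comparisons. Of 181 doubly called genes 64 (35.4%) had probes of opposite direction. RNA quality or amplification may be part of it, but this correlation cannot tell them from other causes. The 0.0797 came from MSCV_A, where 0 probes changed at least 2-fold.

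Genes of thymic stroma and epithelium fell at 3 h and 6 h after peptide, and at 12 h the list was not called (camera adjusted p = 0.782). Slides of series 13 as the whole cause were argued against by the median of -0.342 at 6 h without replicates 1 and 2. A lower share of thymic epithelial cells stays open. At 6 h 11 cortical genes had a median of -0.23 and 9 medullary genes -0.0165, a difference of -0.213 (exact p = 0.158 over 167960 arrangements of genes). Cortical genes fell in 4, 5 and 4 of 11 at 3 h, 6 h and 12 h, with the cortical factor gene Pax1 at -0.82, -1.11 and -1.03, and medullary ones in 1, 1 and 0 of 9. A direct effect of the peptide on these cells was not tested.

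Other groupings of the arrays tested whether chance could give the counts. For HDAC7-VP16, 1 of 100 splits, the real one, called as many as 447 probes (highest other 32), and for PMA with ionomycin 1 of 100 called 2057 (highest other 868). MEF2D-VP16 had 1 of 35 splits at 2067 (highest other 57). Among 32 sign patterns each, 1 reached 5975 in the MHC comparison (highest other 0), 446 at 3 h (highest other 1), 753 at 6 h (highest other 4) and 557 at 12 h (highest other 51). Chance was argued against for these, with arrays taken as independent. Chance at the level of slide sets was not tested for them. In the sign patterns the dye column was not turned, so only the real pattern had its dye effect removed. Without a dye term the real counts were 5975 in the MHC comparison and 435, 640 and 712 at 3 h, 6 h and 12 h. The time difference of 674 was reached by 1 of 100 splits, the real one (highest other 556). This argues against chance with arrays taken as independent. It does not argue against slide series, since all arrays at 3 h and 2 of 6 at 6 h and at 12 h are of series 13. With that series as a block 1421 probes differed. For MSCV_A 2 of 100 sign patterns reached 325 (highest other 2448), which argues against chance with the values as deposited, under the same limit on the dye column. Apart from replicate 1, the highest other is the split by dye orientation with replicates 3 and 9 exchanged. It thus measures mainly the dye. These 2 arrays, replicates 3 and 9, are unsettled (0 probes with their sign turned, 1376 unadjusted, limma, and 623 with their dye exchanged). For HDAC7 DP 2 of 100 splits reached 271 (highest other 2060), which points to a structure of the samples. Its arrays come in 4 sets of slides, whose 3 groupings are too few to test. Besides the real 271, setting slides 13, 14, 19 and 20 against 15 to 18 called 3312 probes, and slides 13, 14, 17 and 18 against the others called 0, both by limma. Series 15 against series 14 called 109 probes there, 61 in the HDAC7-VP16 arrays and 30 in those of stimulation. With slides of one set averaged 0 probes passed for HDAC7 DP (622 unadjusted, limma), so chance at the level of sets stays open. For Nur77, 2 of 35 splits reached 1138. The other one (3738) is the split by dye orientation, for which no dye term can be estimated, so it measures the dye and not chance. By the rule set beforehand these 2 of 35 splits leave chance open. Of the 34 splits without the dye split only the real one reached 1138 (highest other 0). That argues against chance only with the dye split set aside and with arrays taken as independent. The rule did not include that step. For MSCV_B the 8 sign patterns are too few (942, highest other 3774, again the dye orientation, and 0 in the rest).

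One array lay apart from the rest of its group for 26 of 487 named genes tested, and chance gives about 1 in 20. The gap was measured against the range of the group, so it can be small where the other arrays lie close together. On MSCV_B arrays these were Nr4a1 at 0.675 (replicate 3) and the interferon gene Ifit1 at 1.78 (replicate 1). On HDAC7-VP16 arrays they were the NF-kB gene Rel at 1.13 (replicate 5) and Hes1 at 1.71 (replicate 1), the array whose source name differs. On stimulated empty-virus arrays they were Pdgfrb at -0.419 (replicate 3) and Gadd45g at 2.33 (replicate 7), and with HDAC7 DP Hk2 at 0.472 (replicate 1). MEF2D-VP16 replicate 3 stood out for Ndrg1 (1.13) and, by little, for Selenbp1 (1.81 against 1.92 to 1.94 on the other arrays). Replicate 1 did for the caspase gene Casp6 (-0.224) and replicate 2 for the anion exchanger gene Slc4a1 (-0.42). Nur77 replicate 4 stood out for Necab2 (4.16) and the Fc receptor gene Fcgr3 (-0.296). In the MHC comparison replicate 6 did for H2-Ea (4.92) and Trib3 (-1.43), and replicate 2 for the stress gene Ddit4 (2.78). Among peptide arrays these were, at 3 h, Cd69 at 1.65 (replicate 6), and Dusp1 at -0.215 and the complement gene C1qb at -0.109 (both replicate 1). At 6 h they were Hdac7 at -0.804 (replicate 4), Tnfrsf4 at 3.48 (replicate 2), the chemokine receptor gene Ccr8 at 2.08 (replicate 1) and the integrin gene Itga6 at -0.428 (replicate 2). At 12 h they were Hdac7 at -0.009 (replicate 2), and Tgtp1 at 5.31 and Tsc22d3 at 0.331 (both replicate 1).

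A difference between times was tested directly, and 674 probes passed the limma F test. Slide series 13 holds every array at 3 h but only replicates 1 and 2 at 12 h, so series may enter the differences between them. For single genes the series was not taken as a block. Between 12 h and 3 h large gains were in Ifi27l2a (2.38), the transcription adaptor gene Tada1 (2.10), Tgtp1 (1.99), Rtp4 (1.96), Krt8 (1.87), the antiviral gene Ifitm3 (1.84) and Nlrp4c (1.82). The largest losses were in Nolc1 (-1.98), Bcl6 (-1.88), Cdk4 (-1.74), the splicing gene Prpf8 (-1.72), the Golgi gene Golph3 (-1.65), the lipid enzyme gene Hsd17b12 (-1.61), the nucleolar gene Noc2l (-1.61) and Ptpn6 (-1.58).

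The 2 empty-virus groups differed from each other in 416 probes by limma, 191 higher and 225 lower in MSCV_B. Higher were Gm20767 (1.82), Tnfsf4 (1.60), Aen (1.48), Phlda1 (1.34), the damage response gene Ddias (1.32), the protease inhibitor gene Ctla2a (1.32), Ly6c1 (1.29) and the RNA helicase gene Ddx21 (1.29). Lower were Selenbp2 (-3.87), Ndrg1 (-3.36), Ccng2 (-3.05), the glycoprotein hormone gene Stc1 (-3.0), Bnip3 (-2.73), Aldoc (-2.73), the mitochondrial gene Mgarp (-2.28) and Bhlhe40 (-1.99). The groups were hybridised as different sets, so set and culture cannot be told apart here.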

How the results depend on the processing

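The fits that change the 2 unsettled MSCV_A arrays, average slides of one set, take slide series as a block, or leave out slides 13-3 and 13-4 at 3 h, slides 17 and 18 of the MHC comparison or, for the gene lists, replicates 1 and 2 of the peptide arrays were chosen only after the result was seen. Over all settings 6572 values of named genes kept direction and side of the threshold, 1055 lost their call, 15 gained one and 28 changed sign. For gene lists these were 679, 42, 39 and 0.

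A size limit of log2 1 left by construction 0 probes with MSCV_A (1968 at an unadjusted p under 0.05 by limma), 44 with MSCV_B, 55 with HDAC7-VP16, 343 with stimulation, 59 with HDAC7 DP, 522 with MEF2D-VP16, 284 with Nur77, 1219 in the MHC comparison, and 64, 84 and 139 at 3 h, 6 h and 12 h. Without a dye term 20 probes were called with MSCV_B, 284 with HDAC7-VP16 and 365 with Nur77, since dye differences then count as spread. All groups in one fit gave 362 (MSCV_B), 603 (Nur77), 724 (3 h) and 3424 (12 h), and array weights gave 1721, 2022 and 3849 at 3 h, 6 h and 12 h. Slide series 14 alone gave 41 (MSCV_A), 7 (HDAC7-VP16) and 781 (stimulation), and series 15 alone 189, 703, 745 and, with HDAC7 DP, 27. Slide number as a random block gave 542 with MSCV_A. All 16 empty-virus arrays as control gave 238 with HDAC7-VP16. Against untreated cells 3234 (HDAC7 DP) and 2167 (Nur77) were called, since the effect of stimulation or virus is then included. With sets averaged, HDAC7-VP16 had 256, stimulation 535 and HDAC7 DP 0 (622 unadjusted, limma), with fewer values left. MSCV_A had 0 with the sign of both unsettled arrays turned (1376 unadjusted, limma) and 623 with their dye exchanged. Without a pair of slides 3 h had 1447 probes (422 of the 446), 6 h 1906 (730 of the 753) and 12 h 4067. The time difference rose to 2749 without slide series 13, which leaves 6 h and 12 h, to 3264 without slides 13-3 and 13-4 at 3 h and the series 13 slides at 6 h and 12 h, and to 1421 with slide series 13 as a block. Where no reason is given the cause was not tested.

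Leaving out 1 array gave 347 to 448 probes with MSCV_B, 1406 to 1860 with MEF2D-VP16, 677 to 1255 with Nur77, 5117 to 5706 in the MHC comparison, 100 to 654 at 3 h, 279 to 996 at 6 h, 46 to 1832 at 12 h, and 271 to 1615 for the time difference. In the larger groups of cultured cells only replicate 1 of HDAC7-VP16 was left out alone (361 probes).

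Against untreated cells, where the stimulated control is not subtracted, HDAC7 DP values turned positive for Nr4a1 (1.89), Dusp2 (0.40), Irf4 (1.07), Pdcd1 (0.21), Nab2 (2.35), Arc (0.70), Lta (0.68), Gadd45b (1.51) and Cd24a (1.13), and Nur77 values turned negative for the kinase inhibitor gene Pik3ip1 (-0.22) and the sterol enzyme gene Lss (-0.14). With all 16 empty-virus arrays, Trib3 (-0.067) and Mef2d (0.042) with MEF2D-VP16 and Sgk1 (0.011) and Itgb7 (0.064) with Nur77 changed sign. H2-D1 went to -0.80 with its probes averaged. Values near 0 also crossed it: Mef2d with HDAC7 DP (-0.056 scaled, -0.046 weighted), Mef2d with MSCV_B (-0.075 to 0.122 without 1 array), Nr4a1 there (-0.036 to 0.307), Mef2d with MEF2D-VP16 (-0.129 to 0.075) and Mef2d at 12 h (-0.104 to 0.041). Over probes called in either comparison rather than over all, correlations moved. HDAC7-VP16 had -0.35 with HDAC7 DP, -0.0845 with MEF2D-VP16, 0.259 with Nur77 and, with peptide at 3 h, 6 h and 12 h, 0.0896, 0.0933 and 0.0029, the last with its sign changed from -0.0875. MEF2D-VP16 and Nur77 had 0.346, HDAC7 DP and stimulation -0.388. With peptide Nur77 had 0.0205, 0.0448 and 0.159, and stimulation 0.263, 0.271 and 0.0728. The cause was not tested for these.

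Filters on missing values were not run because none was missing, and at 3 h leaving out repeated slide numbers leaves 2 arrays and no residual degrees of freedom, so it was not run. Signal over background was not measured, and the limit on precision is the spread between arrays. No paired analysis was possible because the labels number slides, not replicates. Slide series 14 and 15 each hold 4 groups of hybridoma cells, and with series as a block 413 probes were called with MSCV_A, 480 with HDAC7-VP16, 2097 with stimulation and 328 with HDAC7 DP. Of named genes and gene lists in the fits with series as a block, only Hdac7 with HDAC7-VP16 changed its call.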

Other observations

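The grouping of genes described here was chosen after the result was seen, and no test was run beyond the fits already described. A shared core appeared in the hybridoma. Cd28, Pdcd1, Nr4a1 and Cd6 rose with HDAC7-VP16, MEF2D-VP16 and Nur77 alike, though with Nur77 Nr4a1 is the delivered gene itself. They fell with HDAC7 DP in stimulated cells, where chance at the level of slide sets stays open. Nr4a1 was not called there in slide series 14 or 15 alone. Cd28 stood at 3.70, 3.25 and 4.54 over untreated cells on the 3 slide sets of HDAC7-VP16, at 3.53 with MEF2D-VP16 and at 3.09 with Nur77, against 0.17 with MSCV_A and -0.28 with MSCV_B. Hdac5 parted the constructs. It rose with HDAC7-VP16 (1.26) and MEF2D-VP16 (3.12), fell with HDAC7 DP (-2.08) and Nur77 (-0.51), and stood at 2.25 on the MHC arrays, which likely means more in DO11.10 than in mhc -/- thymocytes. The call of Hdac5 with Nur77 ended without MSCV_B replicate 2 (-0.56 to -0.48 over all 8 fits), but the fall was larger against untreated cells (-1.17) and with all 16 empty-virus arrays as control (-1.07), called in both. Ahsg and Eno3, genes of liver and muscle, rose with MEF2D-VP16 (4.55 and 3.86) and with Nur77 (6.16 and 3.73), and Eno3 also with HDAC7-VP16 (2.07).

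Egr1 and Egr2, which share inducers with Nr4a1, did not follow it in unstimulated cells. With HDAC7-VP16 Egr1 fell by 1.35 while Egr2 stayed near 0 (0.06, 0.12 and -0.05 over untreated cells on the 3 slide sets), and with Nur77 Egr1 fell by 1.42. In stimulated cells HDAC7 DP left Egr1 at 4.31 on slides 17 and 18 and at 2.50 on slides 19 and 20. With the empty virus Egr1 stood at 2.17 on slides 13 and 14 and at 3.95 on slides 15 and 16. Egr2, in the same order of slides, stood at 4.03 and 2.29 with HDAC7 DP and at 2.91 and 5.04 with the empty virus. A difference between these genes was not tested.

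Hdac7 RNA on the HDAC7-VP16 arrays stood at 0.77 (SD 0.27) in slide series 15 and at 0.22 (SD 0.37) in series 14. At 12 h after peptide Pdcd1 stood at 1.37 on replicates 1 and 2 and at -0.78 on the other 4, and Hdac5 at 0.18 and -1.98. The dye pattern of MSCV_A replicates 3 and 9 correlated with the dye term of the HDAC7-VP16 arrays at -0.668 and -0.673. The other MSCV_A arrays gave 0.362 to 0.837. After removal of the dye effect replicates 3 and 9 correlated with the other MSCV_A arrays at 0.182 and 0.28, within the range of the rest (0.0708 to 0.325).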
